A study of Mus musculus with 50 samples.

How the data were processed

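Colon RNA of 50 mice aged 10 to 12 weeks was measured on 1 Affymetrix array per mouse, from 100 ng of RNA per the labels. Replicate numbers are the numbers in the array titles. Per the submitters' processing notes, signals were made in Expression Console and Transcriptome Analysis Console, whose versions and normalization algorithm are not given in the sources used here. The deposited values are log2 signals per probe set, as checked on their range and on array medians of 6.41 to 6.47. The largest SD of any quantile between arrays was 0.10, so the deposited arrays had nearly the same distribution. No detection calls were among the files used, so no gene was called absent, and dim genes were handled as an alternative.

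The deposited table held 22142 probe sets. Of these, 19527 carried 1 gene symbol and 2615 none. Where a symbol had more than 1 probe set, the 1 with the highest mean was kept and 33 were dropped, which left 19494 genes to test. The mouse assembly GRCm38.p6 served only for gene names and gene order.

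Samples were grouped by genotype and title-number series (1 to 30, 86 to 124), which gave 10 groups of 5 arrays. The FADD IEC-KO and CASP8 IEC-KO genotypes were in both series, Casp8 fl/fl and FADD IEC-KO RIPK3 IEC-KO only in the second, and the other genotypes only in the first. A linear model with 1 mean per group was fitted over all 50 arrays in limma 3.58.1 (R 4.3.3), with 40 residual degrees of freedom and empirical Bayes moderation. Contrasts of the main comparisons stayed within a series, and the contrast of the single knockouts averaged the 2 series. Checks of each single knockout between its 2 series, and of Casp8 fl/fl against Fadd fl/fl, crossed the series. Moderated p-values were adjusted by Benjamini-Hochberg over the 19494 genes, and an adjusted p under 0.05 counted as passing. SEs of single genes come from this fit, and those of list means and clock scores from the SDs of the 2 groups compared. The comparisons were single knockouts against floxed controls and each other, co-deletions against the single knockout and against floxed controls of the same series, the 2 co-deletions of FADD IEC-KO with Zbp1 or Mlkl, and an interaction for Mlkl loss. The floxed control of a series was not always the one of the deleted gene.

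A set of 34 gene lists was written by hand, and the comparisons, lists, naming rule and first set of alternatives were fixed before the data were examined. Lists were tested with camera, with the preset correlation of 0.01 and with a correlation estimated from the arrays, and with fry. Gene lists have fewer measured members than written where a symbol was not on the array (24 of 26 type I interferon genes). Genes raised or lowered by a single knockout were taken from the other series, up to 200 each way, and tested in the co-deletions with fry. Differences of list means used exact two-sided permutation tests.

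The genes given by name followed a fixed rule. They were the 5 targeted genes in every comparison, the 6 largest rises and 6 largest falls that passed and whose groups of arrays did not overlap (without predicted and sex-linked genes), up to 4 members with the smallest adjusted p of each list described, or up to 2 with the largest fold where none passed, the genes named for the single knockout in its co-deletions, and up to 3 members of the clock, immediate early and sex-linked lists.

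These alternatives were pooled series with and without a series term, a fit of the compared arrays alone, quantile normalization, removal of the dimmest 40% of genes, trend and robust moderation, a covariate for sex (read from the Y-linked genes Kdm5d, Eif2s3y and Uty, since Xist was unnamed here), all risen genes in place of 200, a 2-fold requirement, and leaving out each array in turn. Group variance weights, a clock score covariate, and the removal of FADD IEC-KO replicates 22 and 23 together were added after the data were seen. The clock score of an array was the mean of Arntl, Npas2 and Clock minus that of Dbp, Tef, Per2, Per3, Nr1d1, Nr1d2 and Ciart. The procedure was tested on simulated data. Independent normal values were drawn for each gene from its mean and residual spread, equal in all groups. Changes were added to the simulated FADD IEC-KO arrays, compared with simulated Fadd fl/fl arrays at 5 against 5. The procedure recovered 52% of changes of 0.5 log2, 96% of changes of 1 and 100% of changes of 2, with 9 unchanged genes called. Correlated genes and groups of unequal spread, as in the real arrays, were not simulated. Principal components of 3000 genes gave 41.8% and 6.09% of the variance to the first 2. Splits of the arrays into other groups of the same sizes were drawn 100 times with a fixed seed.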

Results

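RNA from the colon of 50 mice was measured on 50 arrays, 1 per mouse, in 8 genotypes. The mice lacked FADD or caspase-8 in intestinal epithelial cells (FADD IEC-KO and CASP8 IEC-KO, 10 arrays each). FADD is the adaptor that brings caspase-8 to death receptors, and caspase-8 starts apoptosis and holds back necroptosis. The other groups had 5 arrays each. They were Fadd fl/fl and Casp8 fl/fl floxed controls, FADD IEC-KO Zbp1 -/-, FADD IEC-KO Mlkl -/-, FADD IEC-KO RIPK3 IEC-KO and CASP8 IEC-KO Mlkl -/-. ZBP1 is a nucleic acid sensor that can engage the kinase RIPK3, and MLKL is the protein that breaks the plasma membrane in necroptosis. The RNA came from colon tissue, whereas the floxed deletions were epithelial, so each value mixes epithelium with muscle, stroma and immune cells. The array titles run in 2 number series, 1 to 30 and 86 to 124, which may be 2 processing batches, since the labels do not say. Differences of the main comparisons were therefore taken within a series. Array medians ran from 6.41 to 6.47 log2 units. The number of arrays limits the precision.

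The targeted genes were read first. Fadd had group means of 7.38 ± 0.18 (SD, n = 5) in Fadd fl/fl and 7.30 ± 0.13 in Casp8 fl/fl, against 6.27 ± 0.20 (n = 10) in FADD IEC-KO and 6.23 to 6.36 in its 3 co-deletions. Casp8 stood at 10.32 ± 0.22 and 10.50 ± 0.15 in the floxed groups, at 9.06 ± 0.25 (n = 10) in CASP8 IEC-KO and at 9.05 ± 0.19 in CASP8 IEC-KO Mlkl -/-. Mlkl was at 7.17 ± 0.12 in FADD IEC-KO Mlkl -/- and 7.31 ± 0.18 in CASP8 IEC-KO Mlkl -/-, below both floxed means of 8.25 ± 0.20 and 8.14 ± 0.23. Zbp1 was at 5.68 ± 0.19 in Fadd fl/fl, 7.27 ± 0.55 in FADD IEC-KO and 5.49 ± 0.50 in FADD IEC-KO Zbp1 -/-. Ripk3 was at 6.60 ± 0.19 in Casp8 fl/fl, 8.21 ± 0.65 in FADD IEC-KO and 6.68 ± 0.13 in FADD IEC-KO RIPK3 IEC-KO. Zbp1 and Ripk3 in their co-deletions were thus near the floxed level, and where each probe set lies relative to the deleted exons is not given in the sources used here, so these 2 genes check those labels only against FADD IEC-KO.

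**Figure D1:**
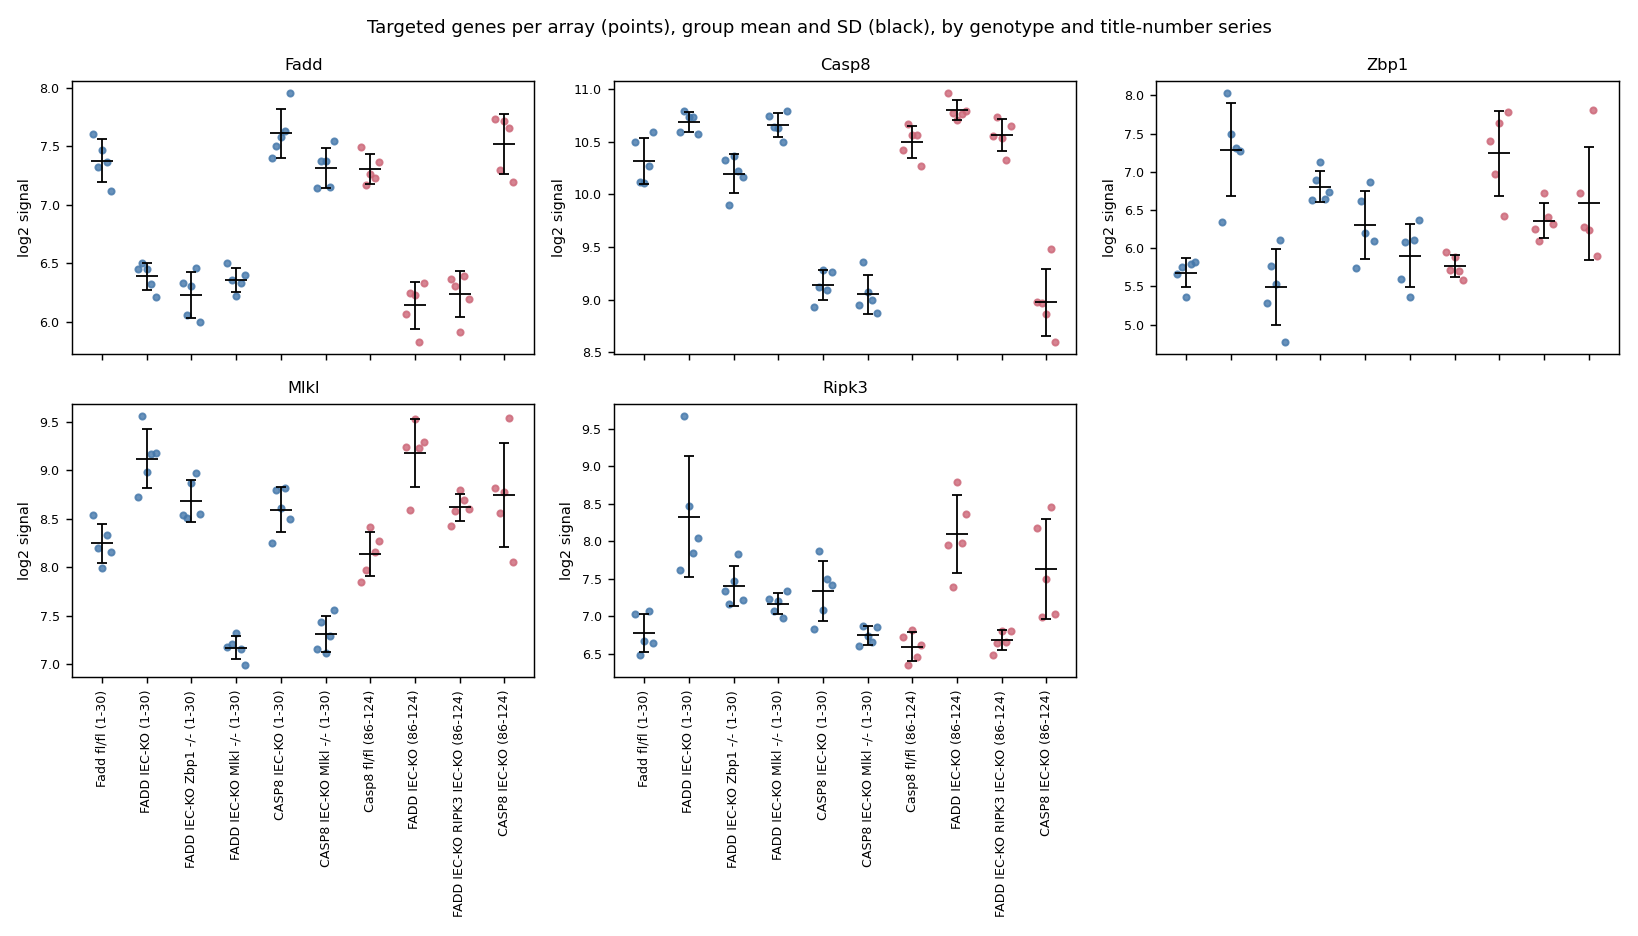
Log2 signal of Fadd, Casp8, Zbp1, Mlkl and Ripk3 (vertical axes) in each array (points) by genotype and title-number series (horizontal axes), with the group mean and SD in black. Mlkl means were 7.17 and 7.31 in the Mlkl -/- groups, and Casp8 means were 9.06 and 9.05 in the CASP8 IEC-KO groups.

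The first comparison asked what epithelial loss of FADD changed. Fadd itself fell by 0.99 log2 units (SE 0.11, n = 5 against 5, limma adjusted p = 3.26e-07). The genes of the same pathway rose: Ripk3 by 1.55 ± 0.25 (SE, limma adjusted p = 9.13e-05), Zbp1 by 1.61 ± 0.27, Mlkl by 0.88 ± 0.17 and Casp8 by 0.37 ± 0.11. The largest rise was that of Retnlb, a goblet cell gene whose protein acts on bacteria, at 5.23 ± 0.79 (limma adjusted p = 4.57e-05). Clca4b rose by 4.65 ± 0.74, Ido1, an interferon-induced enzyme of tryptophan breakdown, by 4.36 ± 0.73, the antibacterial phospholipase Pla2g2a by 4.13 ± 0.54, the inducible nitric oxide synthase Nos2 by 3.94 ± 0.71 and Plet1 by 3.90 ± 0.81. Among genes whose 2 groups of arrays did not overlap, the largest falls were led by Pln, a calcium handling gene of muscle, at -1.84 ± 0.30, then Odf3b, Sycn, Slc37a2, Rnf32 and Casq2, another such gene, at -1.57 ± 0.28.

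All 25 measured genes of interferon-gamma response and antigen presentation rose in FADD IEC-KO, with a median of 1.74 log2 units (camera adjusted p = 2.18e-27, and adjusted p = 0.138 with an estimated correlation). Fry called this list (fry adjusted p = 1.24e-05). Examples were the GTPases Iigp1 at 2.92 ± 0.46 and Igtp at 2.62 ± 0.43, the immunoproteasome subunit Psmb8 at 1.91 ± 0.31 and H2-DMa, which loads class II molecules, at 1.76 ± 0.29. Of 24 type I interferon-stimulated genes 18 rose (21 adjusted over the list alone), among them Oasl2 at 1.86 ± 0.41, Rtp4 at 1.55 ± 0.33, Irf7 at 1.15 ± 0.25 and Bst2 at 0.91 ± 0.19 (adjusted p = 0.192 with an estimated correlation). In the list of necroptosis and death receptor genes 9 of 19 rose and 1 fell (11 and 1 adjusted over the list alone), with the death ligand gene Tnfsf10 at 1.54 ± 0.20 (limma adjusted p = 5.35e-06). That list had adjusted p = 0.188 with an estimated correlation. Among 23 inflammasome and pyroptosis genes 6 rose and 5 fell (6 and 6 adjusted over the list alone). Gsdmd, the pore former of pyroptosis, rose by 0.56 ± 0.12 and Casp4 by 0.84 ± 0.18, whereas Gsdmc2 and Gsdmc3 fell by 0.67 (SE 0.15) and 0.80 (SE 0.17).

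Genes of inflammatory cells rose in the same arrays. Of 23 acute cytokines and chemokines 15 rose (17, with 2 that fell, adjusted over the list alone), including Ccl8 at 2.26 ± 0.25, Tnf at 2.32 ± 0.43, Ccl3 at 2.46 ± 0.61 and Il1b at 3.55 ± 0.86 (adjusted p = 0.213 with an estimated correlation). Of 19 neutrophil markers 13 rose (16 adjusted over the list alone), with the calprotectin genes S100a8 at 3.82 ± 0.89 and S100a9 at 2.62 ± 0.69 (adjusted p = 0.238 with an estimated correlation). In the other series the neutrophil list mean of FADD IEC-KO differed from Casp8 fl/fl by 0.68 ± 0.54 (exact two-sided permutation p = 0.429, n = 5 against 5). Of 18 monocyte and macrophage markers 15 rose (16 adjusted over the list alone), with Fcgr3 at 1.23 ± 0.23 and Ly6c2 at 1.86 ± 0.36 (adjusted p = 0.156 with an estimated correlation). Of 21 T cell and cytotoxic lymphocyte markers 9 rose (9 adjusted over the list alone), with the granzyme gene Gzmb at 0.93 ± 0.19 (adjusted p = 0.208 with an estimated correlation). The plasma cell genes Mzb1 and Jchain rose by 2.2 ± 0.34 and 2.66 ± 0.51, while 5 of the 17 B cell and plasma cell markers rose and the list median was -0.01. The list was called upward by camera (adjusted p = 0.596 with an estimated correlation), so its median and its test differed in sign.

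In the epithelium and muscle lists, 14 of 24 antimicrobial and stress genes rose and 1 fell (15 and 1 adjusted over the list alone), with Duoxa2, a maturation factor of an epithelial oxidase, at 2.76 ± 0.46 (adjusted p = 0.138 with an estimated correlation). Of 25 proliferation genes 8 rose (11 adjusted over the list alone), including Mcm3 at 0.64 ± 0.15 and Rrm2 at 0.84 ± 0.20 (adjusted p = 0.305 with an estimated correlation). Of 13 endoplasmic reticulum stress genes 6 rose (6 adjusted over the list alone), including Asns at 0.93 ± 0.16, Sdf2l1 at 0.72 ± 0.13 and Xbp1 at 0.52 ± 0.09 (adjusted p = 0.138 with an estimated correlation). All 14 smooth muscle markers fell (14 adjusted over the list alone), with a median of -1.16 (adjusted p = 0.138 with an estimated correlation, fry adjusted p = 3.96e-05). Pcp4 stood at -1.70 ± 0.30, Synpo2 at -1.37 ± 0.24, Hspb6 at -1.26 ± 0.22 and Kcnmb1, a subunit of a muscle potassium channel, at -0.82 ± 0.13. Of 27 xenobiotic and steroid metabolism genes 14 fell (16, with 1 that rose, adjusted over the list alone), including the cytochrome gene Cyp2c55 at -2.77 ± 0.64, Abcb1a at -1.17 ± 0.25 and Sult1a1 at -1.11 ± 0.24 (adjusted p = 0.336 with an estimated correlation). Colonocyte markers went both ways (4 of 24 rose and 6 fell, 6 and 6 adjusted over the list alone): the water channel gene Aqp4 rose by 2.05 ± 0.25 and Krt20 by 0.52 ± 0.11, and the carbonic anhydrase gene Car1 fell by 1.06 (SE 0.20). Goblet cell markers also split, 3 up and 3 down of 18 (3 and 3 adjusted over the list alone), with Spink4 at 0.93 ± 0.17 and Klk1 at -0.64 ± 0.15.

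In all, 1674 genes rose and 1976 fell of 19494 in FADD IEC-KO (limma, Benjamini-Hochberg adjusted p under 0.05). Replicates 22 and 23 held the highest neutrophil list means of these 5 FADD IEC-KO arrays, and without them 682 genes changed. Of 63 individually followed genes that passed, 43 passed without those 2 arrays. The 20 that did not were Casp8, Plet1, Slc37a2, S100a8, S100a9, Il1b, Ccl3, Gsdmc2, Gsdmc3, Irf7, Bst2, Fcgr3, Gzmb, Ctla4, Cyp2c55, Sult1a1, Abcb1a, Rrm2, Klk1 and Postn. The call of Casp8 was also lost with only the 10 arrays fitted, with the clock score as a covariate and in a fit without a single array. A separate comparison of the other 5 FADD IEC-KO arrays (title numbers 86 to 124) with Casp8 fl/fl shared no array with this one. There 620 of the genes that rose also rose (114 by chance) and 408 of those that fell also fell (83.9 by chance), with 12 in opposite directions.

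**Figure D2:**
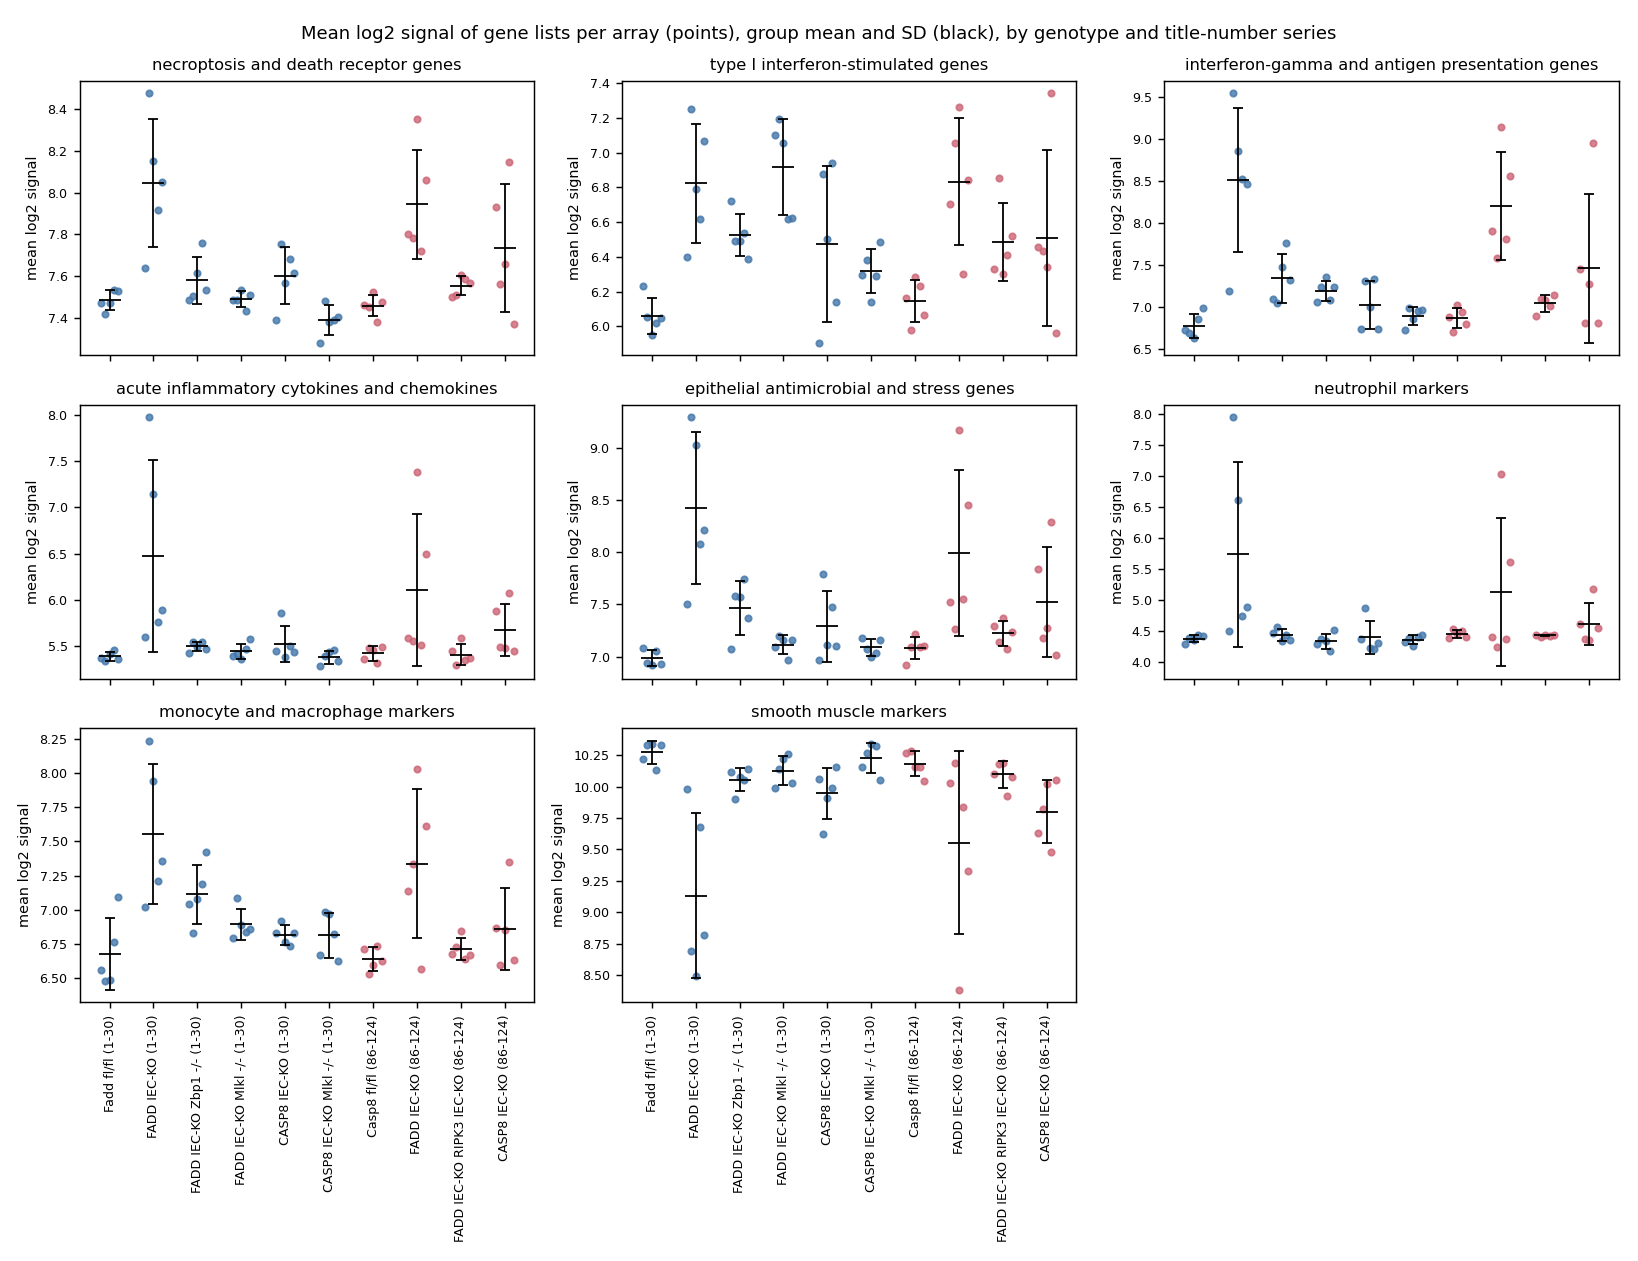
Mean log2 signal of 8 gene lists (vertical axes) in each array (points) by genotype and title-number series (horizontal axes), with the group mean and SD in black. Smooth muscle means averaged 9.13 in FADD IEC-KO (1-30) and 10.27 in Fadd fl/fl, and type I interferon means averaged 6.92 in FADD IEC-KO Mlkl -/- and 6.06 in Fadd fl/fl.

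CASP8 IEC-KO was compared with Casp8 fl/fl to see what epithelial loss of caspase-8 changed. Casp8 fell by 1.52 log2 units (SE 0.11, n = 5 against 5, limma adjusted p = 3.52e-13), Ripk3 rose by 1.03 ± 0.25 and Mlkl by 0.61 ± 0.17, and Zbp1 was at 0.82 ± 0.27 (limma adjusted p = 0.0826). Among genes whose 2 groups of arrays did not overlap, the largest rises included Ly6m at 1.69 ± 0.45, Ddah1, an enzyme that breaks down an inhibitor of nitric oxide synthesis, at 1.62 ± 0.37, Krt84 at 1.22 ± 0.30 and the tight junction gene Cldn4 at 1.15 ± 0.24 (limma adjusted p = 0.0114). The largest falls by the same rule included the pentraxin genes Mptx1 and Mptx2 at -1.66 ± 0.43 and -1.49 ± 0.39, and the matrix genes Lum and Dpt at -1.0 ± 0.23 and -0.83 ± 0.20. The matrix gene Dcn stood at -0.69 ± 0.17, and 2 of 13 endothelial markers fell (4 adjusted over the list alone), Pecam1 at -0.49 ± 0.12 and Lyve1 at -0.82 ± 0.22 (adjusted p = 0.606 with an estimated correlation). In CASP8 IEC-KO of the other series against Fadd fl/fl Pecam1 was at 0.20 ± 0.12 (limma adjusted p = 0.534) and Lyve1 at -0.32 ± 0.22 (limma adjusted p = 0.577), with none of the 13 endothelial markers past the limma threshold (0 adjusted over the list alone, list median 0.02). All 14 smooth muscle markers were lower in both comparisons, with none past that threshold (list medians -0.35 here and -0.31 in the other series). Camera called that list in both (adjusted p = 0.640 and 0.626 with an estimated correlation).

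In the fixed lists, 3 of 25 proliferation genes rose in CASP8 IEC-KO (9 adjusted over the list alone): Mcm5 at 0.60 ± 0.16, Ccnb2 at 0.58 ± 0.16 and Ube2c at 0.66 ± 0.18 (adjusted p = 0.606 with an estimated correlation). All 25 were higher, with a median of 0.37. In the other series against Fadd fl/fl all 25 were higher too, but none passed (0 adjusted over the list alone, list median 0.20). Of the 19 necroptosis and death receptor genes 4 rose and 1, Casp8, fell against Casp8 fl/fl (9 and 1 adjusted over the list alone), with the adaptor gene Tradd at 0.27 ± 0.07 (adjusted p = 0.606 with an estimated correlation). Aqp4 rose by 1.12 ± 0.25, Krt20 by 0.47 ± 0.11, the peptide hormone gene Pyy by 0.59 ± 0.15 and the cytokine gene Il23a by 0.50 ± 0.13, and Clca1 of goblet cells fell by 0.54 (SE 0.15). None of the 25 interferon-gamma genes passed alone in limma (0 adjusted over the list alone), although their median was 0.50 and camera called the list (adjusted p = 6.6e-07, and adjusted p = 0.633 with an estimated correlation). The list mean was 8.96 in CASP8 IEC-KO replicate 104 and 6.81 to 7.45 in the other 4 arrays, against 6.71 to 7.02 in Casp8 fl/fl. Cxcl9 was at 1.40 ± 0.60 (limma adjusted p = 0.190), Gbp2 at 1.12 ± 0.44 (limma adjusted p = 0.156), Clca4b at 2.41 ± 0.74 (limma adjusted p = 0.0646) and Nos2 at 1.80 ± 0.71 (limma adjusted p = 0.154). The 24 type I interferon genes were all higher but none passed in limma, and 23 were higher in the other series. Camera called this list here (adjusted p = 5.88e-05, and adjusted p = 0.640 with an estimated correlation). In all, 350 genes rose and 129 fell. Only Casp8 passed in the fit restricted to these 10 arrays, so apart from Casp8 the count depended on the spread shared with the other groups. It also depended on single arrays, with 1 gene without CASP8 IEC-KO replicate 87 and 1070 without replicate 108. CASP8 IEC-KO of title numbers 1 to 30 against Fadd fl/fl, which shared no array with this comparison, had 11 rises and 13 falls, of which 5 and 2 were among those found here. Of 479 genes, 182 rose and 66 fell as in FADD IEC-KO (30.1 and 13.1 by chance) and 1 went the opposite way. The fit with both series pooled changed the list of followed genes: 15 of 26 passed there, without Lum, Dpt, Mptx1, Mptx2, Krt84, Clec4n, Tradd, Ccnb2, Pecam1, Lyve1 and Pyy.

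The single knockouts were then compared within each series (10 arrays against 10), to ask how they differed. Fadd was higher by 1.30 ± 0.08 and Casp8 lower, at -1.68 ± 0.08, in CASP8 IEC-KO (limma adjusted p = 9.25e-21 for Casp8). Zbp1 stood at -0.82 ± 0.19, Ripk3 at -0.72 ± 0.18 and Mlkl at -0.48 ± 0.12, all lower in CASP8 IEC-KO. Ido1 was lower by a log2 difference of -2.92 ± 0.52, Retnlb by -2.63 ± 0.56, Lcn2, which withholds iron from bacteria, by -1.79 ± 0.45, Ccl8 by -1.51 ± 0.18, the membrane mucin gene Muc1 by -1.36 ± 0.16 and Tnfsf10 by -1.05 ± 0.14 (limma adjusted p = 1.07e-05). Pisd-ps3 was higher by 1.27 ± 0.11, Myo3a by 0.94 ± 0.16 and Zfp532 by 0.81 ± 0.10, the rises among genes whose 10 and 10 arrays did not overlap. Hgfac at -0.51 ± 0.08 and Wdr76 at -0.38 ± 0.08 were the falls of that kind followed here. Pisd-ps3 also differed between the floxed controls, where it was 1.07 ± 0.16 higher in Casp8 fl/fl than in Fadd fl/fl (limma adjusted p = 0.000699). Its difference between the knockouts is thus not separated from one between the floxed lines. These floxed controls come from different number series, so that check does not separate line from series. Zfp532 was higher by 0.72 ± 0.15 in FADD IEC-KO of title numbers 86 to 124 than of 1 to 30 (limma adjusted p = 0.0231).

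By list, 23 of 25 interferon-gamma genes were lower in CASP8 IEC-KO (25 adjusted over the list alone), with Iigp1 at -1.89 ± 0.33, Psmb8 at -1.29 ± 0.22, H2-DMa at -1.26 ± 0.21 and Tap2 at -0.53 ± 0.08. This call held with the correlation estimated (camera adjusted p = 0.0484 with an estimated correlation). Of 18 macrophage markers 14 fell (17 adjusted over the list alone), with Ccr2 at -0.97 ± 0.20 and the complement gene C1qa at -0.62 ± 0.13 (adjusted p = 0.0881 with an estimated correlation). Of 19 neutrophil markers 10 fell (16 adjusted over the list alone), with S100a8 at -2.25 ± 0.63 and Csf3r at -1.01 ± 0.24 (adjusted p = 0.129 with an estimated correlation). Of 14 smooth muscle markers 11 rose (14 adjusted over the list alone), with Myh11 at 0.64 ± 0.17 and Hspb6 at 0.63 ± 0.16 (adjusted p = 0.129 with an estimated correlation), and Cyp2c55 stood at 1.62 ± 0.45. Of 18 goblet markers 7 fell and 1 rose (9 and 2 adjusted over the list alone), with Tff3 at -0.40 ± 0.08 and Muc2 at -0.24 ± 0.04 (adjusted p = 0.165 with an estimated correlation). The tuft cell genes Dclk1, Trpm5 and Il17rb rose by 0.43 ± 0.10, 0.56 ± 0.14 and 0.53 ± 0.13, the 3 that passed of 13 (3, with 1 that fell, adjusted over the list alone). In all, 415 genes were higher and 585 lower (limma, Benjamini-Hochberg). Without FADD IEC-KO replicates 22 and 23 the count was 135, and 17 of 32 followed genes passed, not Zbp1, Mlkl, Ripk3, S100a8, Csf3r, Myh11, Hspb6, Cyp2c55, Retnlb, Lcn2, Ccr2, C1qa or the 3 tuft cell genes. With only these 20 arrays fitted, 41 genes and 12 of the 32 followed genes passed, and those lost were the same 15 with Ido1, Iigp1, Psmb8, H2-DMa and Muc2. A regrouping of the arrays gave more genes than the real groups (2141).

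**Figure D3:**
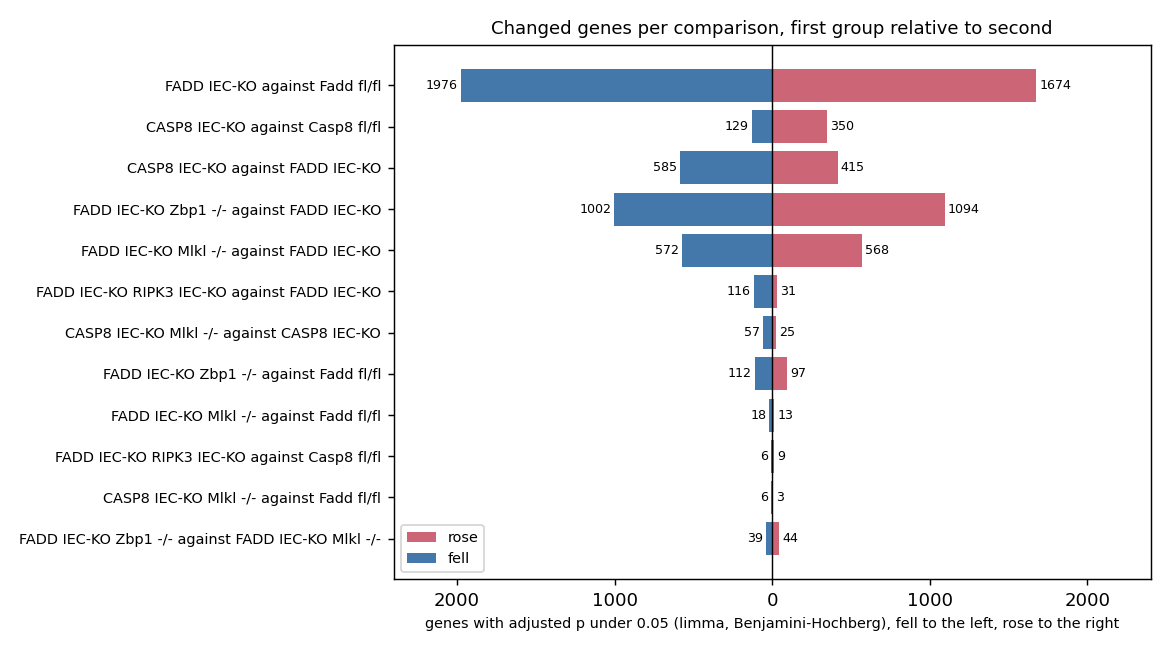
Number of genes with a Benjamini-Hochberg adjusted p under 0.05 in limma (horizontal axis, falls to the left and rises to the right) for each comparison (vertical axis). The bars run from 1674 rises and 1976 falls in FADD IEC-KO against Fadd fl/fl to 3 rises and 6 falls in CASP8 IEC-KO Mlkl -/- against Fadd fl/fl. Counts of co-deletions against floxed controls depended on how the spread was estimated.

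FADD IEC-KO Zbp1 -/- was set against FADD IEC-KO of the same series, to ask what loss of ZBP1 changed. Zbp1 fell by 1.80 log2 units (SE 0.27, n = 5 against 5, limma adjusted p = 6.65e-05), Ripk3 by 0.92 (SE 0.25) and Casp8 by 0.49 (SE 0.11), with Fadd at -0.16 ± 0.11 (limma adjusted p = 0.404). Retnlb was lower by a difference of -4.77 ± 0.79 (limma adjusted p = 0.000277), S100a8 of -3.51 ± 0.89, Clca4b of -3.22 ± 0.74, the cytokine gene Il1b of -3.25 ± 0.86, Pla2g2a of -2.54 ± 0.54, Ccl3 of -2.41 ± 0.61 and Cxcl2 of -2.33 ± 0.63. Odf3b, Naaladl1, Pln and Casq2 rose by 2.15 ± 0.35, 1.74 ± 0.30, 1.70 ± 0.30 and 1.46 ± 0.28, and C1qtnf3 and Aspn by 1.46 ± 0.31 and 1.34 ± 0.28. Tnfsf10, at -0.23 ± 0.20, did not pass (limma adjusted p = 0.529).

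Among the lists, 24 of 25 interferon-gamma genes fell with Zbp1 loss (25 adjusted over the list alone), with Iigp1 at -2.11 ± 0.46, Psmb8 at -1.52 ± 0.31 and the checkpoint ligand gene Cd274 at -1.30 ± 0.32 (adjusted p = 0.180 with an estimated correlation). Only Bst2 fell of the 24 type I interferon genes (1 adjusted over the list alone), at -0.83 ± 0.19, with Oasl2 at -0.39 ± 0.41 (adjusted p = 0.543 for the list with an estimated correlation). Of 19 neutrophil markers 12 fell (16 adjusted over the list alone), with Retnlg at -2.42 ± 0.68 and Ltf at -1.15 ± 0.30 (adjusted p = 0.266 with an estimated correlation), and the myeloid adaptor gene Tyrobp stood at -1.05 ± 0.22. Of 23 acute cytokines and chemokines 9 fell (19 adjusted over the list alone), including Tnf at -1.75 ± 0.43 (adjusted p = 0.206 with an estimated correlation). Of 14 smooth muscle markers 13 rose (14 adjusted over the list alone), with Synpo2 at 1.22 ± 0.24, the contractile regulator Cnn1 at 1.11 ± 0.22 and Kcnmb1 at 0.73 ± 0.13 (adjusted p = 0.180 with an estimated correlation). Of 27 xenobiotic and steroid metabolism genes 10 rose (18 adjusted over the list alone), with Sult1a1 at 1.22 ± 0.24 and Hsd17b2 at 0.62 ± 0.13 (adjusted p = 0.206 with an estimated correlation). In epithelial lists Slc37a2 rose by 1.92 ± 0.35, and the sodium channel gene Scnn1g, Cldn4 and Spink4 stood at -1.75 ± 0.37, -1.15 ± 0.24 and -0.78 ± 0.17. In all, 1094 genes rose and 1002 fell (limma, Benjamini-Hochberg). Without FADD IEC-KO replicates 22 and 23 the count was 121, and 5 of 35 followed genes passed: Zbp1, Odf3b, Pln, Retnlb and Scnn1g. Scnn1g did not pass in the pooled fit without a series term (-0.99, limma adjusted p = 0.0938), and it differed by -1.51 ± 0.37 between the 2 series of FADD IEC-KO (limma adjusted p = 0.0485). With only the 10 arrays fitted 184 genes and 11 of 35 followed genes passed, and the fits that pooled both series gave 889 with a series term and 1016 without one.

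FADD IEC-KO Mlkl -/- was set against FADD IEC-KO in the same way. Mlkl fell by 1.95 log2 units (SE 0.17, n = 5 against 5, limma adjusted p = 8.17e-11) and Ripk3 by 1.16 (SE 0.25), with Zbp1 at -0.48 ± 0.27 (limma adjusted p = 0.315). Retnlb had the largest fall at -5.14 ± 0.79 (limma adjusted p = 0.000313), then S100a8 at -4.07 ± 0.89, Clca4b at -3.94 ± 0.74, Nos2 at -3.87 ± 0.71, Plet1 at -3.27 ± 0.81 and Lcn2 at -3.08 ± 0.63. Tppp3 rose by 1.81 ± 0.35, Pln by 1.63 ± 0.30, Pcp4 by 1.55 ± 0.30, C1qtnf3 by 1.5 ± 0.31, Abi3bp by 1.40 ± 0.25 and Aspn by 1.28 ± 0.28. Of 25 interferon-gamma genes 23 fell (25 adjusted over the list alone), with Iigp1 at -2.53 ± 0.46, Gbp2 at -2.13 ± 0.44 and the transcription factor gene Irf1 at -0.89 ± 0.18 (adjusted p = 0.0637 with an estimated correlation). None of the 24 type I interferon genes passed in limma (0 adjusted over the list alone, list median 0.08): Oasl2 was at 0.64 ± 0.41 (limma adjusted p = 0.395) and Rtp4 at 0.62 ± 0.33 (limma adjusted p = 0.286).

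With Mlkl loss 12 of 24 epithelial antimicrobial and stress genes fell and 1 rose (16 and 1 adjusted over the list alone), with Pla2g2a at -3.01 ± 0.54 (adjusted p = 0.0637 with an estimated correlation). Of 19 neutrophil markers 12 fell (16 adjusted over the list alone), with S100a9 at -2.61 ± 0.69 and Ltf at -1.24 ± 0.30 (adjusted p = 0.173 with an estimated correlation). Of 18 macrophage markers 8 fell (12 adjusted over the list alone), with the endotoxin co-receptor gene Cd14 at -1.22 ± 0.25 (adjusted p = 0.173 with an estimated correlation). Ccl8, Tnfsf10 and Muc1 stood at -1.71 ± 0.25, -1.09 ± 0.20 and -1.42 ± 0.22. All 14 smooth muscle markers rose (14 adjusted over the list alone), with Casq2 at 1.62 ± 0.28 and Synpo2 at 1.22 ± 0.24 (adjusted p = 0.0727 with an estimated correlation). Cyp2c55 rose by 2.65 ± 0.64, Car1 by 1.02 ± 0.20 and the transporter gene Abcb1a by 1.00 ± 0.25. In all, 568 genes rose and 572 fell (limma, Benjamini-Hochberg). Without FADD IEC-KO replicates 22 and 23 the count was 8, and Mlkl and Ccl8 were the only ones of 29 followed genes that passed. The pooled-series fit gave 567 genes and the fit of the 10 arrays alone gave 51, with 11 of 29 followed genes.

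FADD IEC-KO RIPK3 IEC-KO was set against the FADD IEC-KO arrays of title numbers 86 to 124. Ripk3 fell by 1.41 log2 units (SE 0.25, n = 5 against 5, limma adjusted p = 0.00402), with Mlkl at -0.56 ± 0.17 (limma adjusted p = 0.0912) and Zbp1 at -0.88 ± 0.27 (limma adjusted p = 0.0963). The falls were led by the interferon-induced GTPase genes Tgtp2 at -2.74 ± 0.58, Iigp1 at -2.21 ± 0.46 and Gbp2 at -1.88 ± 0.44, with Serpina3n at -1.80 ± 0.41, Ccl8 at -1.58 ± 0.25, Ddah1 at -1.57 ± 0.37 and Tnfsf10 at -1.05 ± 0.20. Capsl rose by 1.10 ± 0.25, the creatine transporter gene Slc6a8 by 0.73 ± 0.13 and Dio1, which activates thyroid hormone, by 0.68 ± 0.17. Of 25 interferon-gamma genes 7 fell (23 adjusted over the list alone), with Tap1 at -1.37 ± 0.32 and H2-DMa at -1.31 ± 0.29 (adjusted p = 0.176 with an estimated correlation). The complement gene C1qb and the perforin gene Prf1 stood at -0.75 ± 0.18 and -0.54 ± 0.14. The fatty acid oxidation genes Acadvl and Hadha rose, each by 0.31, with SE 0.07 and 0.08, the 2 that passed of 17 (2 adjusted over the list alone, adjusted p = 0.407 with an estimated correlation). Retnlb was at -2.77 ± 0.79 (limma adjusted p = 0.0744) and Clca4b at -2.66 ± 0.74 (limma adjusted p = 0.0683). In all, 31 genes rose and 116 fell (limma, Benjamini-Hochberg). The count was 24 without FADD IEC-KO RIPK3 IEC-KO replicate 113, 411 without FADD IEC-KO replicate 95 and 651 with both series pooled. Of 20 followed genes 4 passed whichever array was left out, namely Ripk3, Slc6a8, Ccl8 and Tnfsf10. Slc6a8 and Acadvl did not pass with both series pooled (0.50 and 0.20, limma adjusted p = 0.0512 and 0.131). Both also differed between the 2 series of FADD IEC-KO, at -0.69 ± 0.13 and -0.32 ± 0.07 for title numbers 86 to 124 against 1 to 30 (limma adjusted p = 0.0104 and 0.0355).

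CASP8 IEC-KO Mlkl -/- was set against CASP8 IEC-KO of title numbers 1 to 30. Mlkl fell by 1.28 log2 units (SE 0.17, n = 5 against 5, limma adjusted p = 2.37e-05), and Ripk3 was at -0.60 ± 0.25 (limma adjusted p = 0.289). Ly6m, Mgat4c, Aqp4, the hair keratin gene Krt36 and Dgat2, an enzyme of triglyceride synthesis, were lower by differences of -1.93 ± 0.45, -1.32 ± 0.27, -1.20 ± 0.25, -1.13 ± 0.21 and -0.98 ± 0.22. Fkbp1b rose by 1.08 ± 0.25, the thyroid hormone receptor gene Thra by 0.70 ± 0.11 (limma adjusted p = 0.00144), the alarmin gene Il33 by 0.55 ± 0.12 and Clock by 0.37 ± 0.09. Pla2g2a was at -1.56 ± 0.54 (limma adjusted p = 0.179) and Cldn4 at -0.71 ± 0.24 (limma adjusted p = 0.179). No list with a camera call kept it when the correlation was estimated, the endoplasmic reticulum stress genes having a median of -0.18 (adjusted p = 0.616 with an estimated correlation). In all, 25 genes rose and 57 fell (limma, Benjamini-Hochberg). The clock genes were apart in this group (score 2.21 ± 0.45, SD, against 0.20 ± 1.41 in CASP8 IEC-KO). With the score as a covariate, added after the data were seen, 27 genes passed, without Fkbp1b, Gde1, Il33, Prl3a1, Ly6m, Dgat2 and Clock. Clock is itself part of the score, so the loss of its call could follow from that alone. Mlkl, Thra and Krt36 were the 3 of 13 followed genes that passed whichever array was left out, and Krt36, Aqp4, Mgat4c, Fkbp1b, Srcin1, Gde1, Il33 and Clock did not pass with only the 10 arrays fitted. The count was 21 without CASP8 IEC-KO Mlkl -/- replicate 8 and 422 with both series of CASP8 IEC-KO pooled.

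Each co-deletion was tested for a lowering of the genes raised by the single knockout. These genes were chosen in the other number series, so no array entered the group means compared in both steps. The spread in both steps came from the fit of all 50 arrays, so the steps were not fully separate. The 200 genes with the strongest rise in FADD IEC-KO against Casp8 fl/fl were followed in FADD IEC-KO Zbp1 -/- against FADD IEC-KO. Their median was -0.65 log2 units, with 183 of 200 lower (fry, a rotation test, two-sided p = 0.00152). Fry compared 5 arrays against 5 within the fit of all 50 arrays. In FADD IEC-KO Mlkl -/- the median was -0.72 with 190 of 200 lower (fry p = 5.51e-05). For FADD IEC-KO RIPK3 IEC-KO, with genes chosen in title numbers 1 to 30, it was -0.83 with 198 lower (fry p = 0.00311). For CASP8 IEC-KO Mlkl -/-, with genes chosen in CASP8 IEC-KO of the other series, it was -0.22 with 187 lower (fry p = 0.00119). Genes that fell in the single knockouts had medians of 0.41, 0.43, 0.48 and 0.13 in the same order. Against floxed controls the risen genes were still higher in FADD IEC-KO Zbp1 -/-, by a median of 0.44 (fry p = 0.00741). The corresponding medians were 0.26 in FADD IEC-KO Mlkl -/- (fry p = 0.0892), 0.16 in FADD IEC-KO RIPK3 IEC-KO (fry p = 0.502) and -0.05 in CASP8 IEC-KO Mlkl -/- (fry p = 0.495). Without FADD IEC-KO replicates 22 and 23 the value for FADD IEC-KO Zbp1 -/- was -0.40 and did not pass (fry p = 0.0874). With all risen genes in place of the 200 strongest, the medians were -0.14, -0.20, -0.16 and -0.14 for FADD IEC-KO Zbp1 -/-, FADD IEC-KO Mlkl -/-, FADD IEC-KO RIPK3 IEC-KO and CASP8 IEC-KO Mlkl -/-, and each still passed (fry p = 0.0156, 9.04e-05, 0.0120 and 0.00467).

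**Figure D4:**
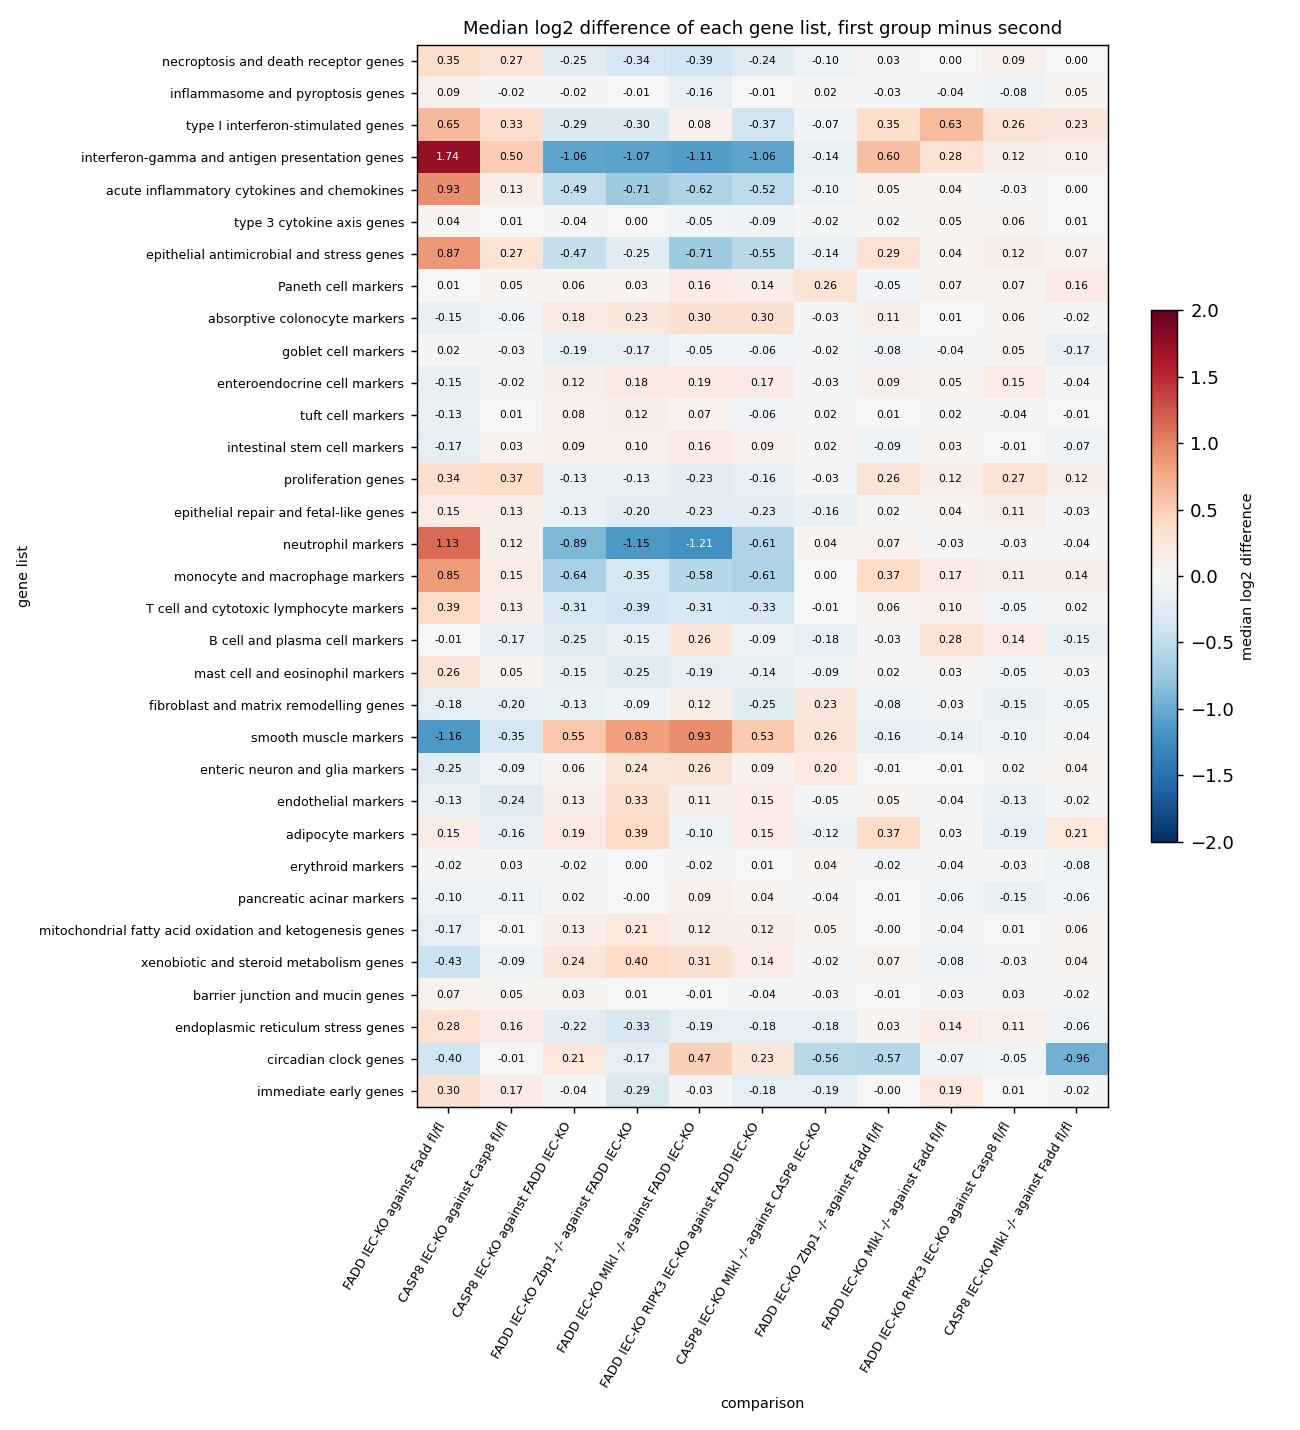
Median log2 difference of the measured members of each of 33 gene lists (vertical axis) in 11 comparisons (horizontal axis), first group minus second, printed in each cell and coloured from blue (lower) to red (higher). The interferon-gamma list reads 1.74 in FADD IEC-KO against Fadd fl/fl and -1.07, -1.11 and -1.06 with loss of ZBP1, MLKL or epithelial RIPK3.

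The co-deletions were also compared with floxed controls, to see what still differed. In FADD IEC-KO Zbp1 -/- against Fadd fl/fl, Fadd was at -1.15 ± 0.11 (n = 5 against 5, limma adjusted p = 5.22e-09) and Zbp1 at -0.19 ± 0.27 (limma adjusted p = 0.852). Aqp4 rose by 2.01 ± 0.25, Ccl8 by 1.55 ± 0.25, Ddah1 by 1.5 ± 0.37, the epithelial oxidase gene Nox1 by 1.44 ± 0.30, Tnfsf10 by 1.31 ± 0.20, Casp4 by 0.79 ± 0.18 and the acute phase gene Saa1 by 0.54 ± 0.12. Sh3bgrl and Uprt, 2 genes of the X chromosome, fell by 1.22 (SE 0.12) and 1.02 (SE 0.12), Anxa8 by 1.28 (SE 0.30), Hspb7 by 1.17 (SE 0.31) and the vesicle fusion genes Snap25 and Sytl2 by 0.85 (SE 0.18) and 0.43 (SE 0.11). None of the 24 type I interferon genes passed in limma (8 adjusted over the list alone), with Oasl2 at 1.46 ± 0.41 (limma adjusted p = 0.0633), and camera called the list (adjusted p = 0.615 with an estimated correlation). In all, 97 genes rose and 112 fell (limma, Benjamini-Hochberg). The count was 68 without Fadd fl/fl replicate 28 and 75 with the clock score as a covariate, where Nox1, Ddah1, Casp4, Saa1, Ces2e, Anxa8, Hspb7 and Sytl2 no longer passed. With only the 10 arrays fitted it was 106, without Acta1, Nox1, Saa1 and Casp4. Of 17 followed genes 8 passed whichever array was left out, not Snap25, Gfra2, Ddah1, Ces2e, Anxa8, Hspb7, Saa1, Casp4 or Sytl2.

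In FADD IEC-KO Mlkl -/- against Fadd fl/fl, the 5 largest rises were type I interferon-stimulated genes. Fadd and Mlkl were at -1.02 ± 0.11 and -1.07 ± 0.17 (n = 5 against 5, limma adjusted p = 2.96e-07 and 0.000409). Oasl2 rose by 2.5 ± 0.41, Rtp4 by 2.17 ± 0.33, Ifit1, which binds viral RNA, by 1.99 ± 0.41, the interferon regulator gene Irf7 by 1.53 ± 0.25 and the ubiquitin-like modifier gene Isg15 by 1.41 ± 0.32. Of the 24 genes in that list 8 rose (19 adjusted over the list alone), with a median of 0.63, and the call held with the correlation estimated (camera adjusted p = 2.35e-34, and adjusted p = 0.0187 with an estimated correlation). Across all comparisons, this call and that of the interferon-gamma list between the single knockouts were the 2 camera calls that held with an estimated correlation. Fry, adjusted over the 34 lists, called 19 lists in FADD IEC-KO against Fadd fl/fl and 14 between the single knockouts. With loss of Zbp1, Mlkl and RIPK3 in FADD IEC-KO it called 17, 12 and 4. Against floxed controls it called 0, 1 and 1 in the same order, and 2 in CASP8 IEC-KO Mlkl -/-. In CASP8 IEC-KO against Casp8 fl/fl and with Mlkl loss in CASP8 IEC-KO it called 0. It also called 0 between the 2 co-deletions with Zbp1 or Mlkl loss and for the interaction. Aqp4 rose by 1.29 ± 0.25, and Pot1b, Parp16, Pcmtd2 and Mapk1ip1 fell by 0.54 to 0.59. The inflammation genes Retnlb and S100a8 were at 0.09 ± 0.79 and -0.25 ± 0.89 (limma adjusted p = 0.987 and 0.968). In all, 13 genes rose and 18 fell (limma, Benjamini-Hochberg). Group variance weights gave a higher count, listed below with the other alternatives. The count was 8 without Fadd fl/fl replicate 29 and 72 without replicate 26, and Fadd, Mlkl, Oasl2, Rtp4 and Irf7 were the 5 of 12 followed genes that passed whichever array was left out.

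FADD IEC-KO RIPK3 IEC-KO against Casp8 fl/fl had Fadd at -1.07 ± 0.11 (n = 5 against 5, limma adjusted p = 6.74e-08) and Ripk3 at 0.09 ± 0.25 (limma adjusted p = 0.944). Abcg5, a sterol exporter gene, rose by 1.06 ± 0.22, Tuba4a by 0.83 ± 0.17, and the DNA replication genes Mcm6, Fen1 and Nasp by 0.71 ± 0.15, 0.66 ± 0.13 and 0.53 ± 0.10. Of 25 proliferation genes 1 rose (4 adjusted over the list alone, adjusted p = 0.832 with an estimated correlation). Pisd-ps3 fell by 0.79 (SE 0.16), and Ide, Defa35, Pot1b and Colec11 by 0.59, 0.59, 0.52 and 0.47. Pisd-ps3 and Ide were also higher in Casp8 fl/fl than in Fadd fl/fl, by 1.07 ± 0.16 and 0.64 ± 0.12 (limma adjusted p = 0.000699 and 0.0200). Their falls are thus not separated from a difference between the floxed lines, which here also differ in number series. Irf7 was at 1.01 ± 0.25 (limma adjusted p = 0.106) and Aqp4 at 0.78 ± 0.25 (limma adjusted p = 0.228). In all, 9 genes rose and 6 fell, and 1 passed without FADD IEC-KO RIPK3 IEC-KO replicate 112. In CASP8 IEC-KO Mlkl -/- against Fadd fl/fl, Casp8 was at -1.27 ± 0.11 and Mlkl at -0.93 ± 0.17 (n = 5 against 5, limma adjusted p = 2.01e-10 and 0.0092). Prelid2, a gene of mitochondrial lipid transfer, fell by 0.78 (SE 0.11) and the calcium pump gene Atp2c2 by 0.47 (SE 0.09), and in all 3 genes rose and 6 fell. More genes passed with only the compared arrays fitted and with group variance weights, as listed below, so the low count does not show a return to control levels. The count was 2 without Fadd fl/fl replicate 26 and 23 without replicate 30, and Mlkl and Atp2c2 were among the 4 of 6 followed genes that lost their call in a fit without a single array. Prelid2 was also lower in Casp8 fl/fl than in Fadd fl/fl, at -0.54 ± 0.11 (limma adjusted p = 0.0437). Its fall is thus not separated from a difference between the floxed lines, which here also differ in number series. The clock genes Dbp and Ciart were at -2.58 ± 0.72 and -2.45 ± 0.67 (limma adjusted p = 0.188 and 0.178). None of the 15 clock genes passed over all genes in limma (3 rose and 10 fell adjusted over the list alone). Camera and fry called that list (camera adjusted p = 0.000179, and adjusted p = 0.116 with an estimated correlation, fry adjusted p = 0.0381). Both also called the 12 Paneth cell markers upward (camera adjusted p = 0.0258, and adjusted p = 0.116 with an estimated correlation, fry adjusted p = 0.0258). Their median was 0.16, and 0 passed in limma. The floxed controls were Fadd fl/fl, the ones present in that series.

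FADD IEC-KO Zbp1 -/- and FADD IEC-KO Mlkl -/- were compared with each other to ask where loss of ZBP1 and loss of MLKL differed. Mlkl was at 1.52 ± 0.17, Zbp1 at -1.32 ± 0.27 and Casp8 at -0.46 ± 0.11 (n = 5 against 5, limma adjusted p = 1.18e-07, 0.00943 and 0.0405). Tnfsf10, the amino acid transporter gene Slc7a9, Ces2a, Got1 and Cited2 were higher in FADD IEC-KO Zbp1 -/- by 0.86 ± 0.20, 0.85 ± 0.19, 0.79 ± 0.19, 0.79 ± 0.14 and 0.77 ± 0.17, and Gsto1 by 0.38 ± 0.09. Lower there were Hspb7 at -1.27 ± 0.31, Irf7 at -1.11 ± 0.25, Sh3bgrl at -1.11 ± 0.12, Cyb5r3 at -0.90 ± 0.17, Uprt at -0.85 ± 0.12, the immediate early gene Fosb at -0.78 ± 0.16 and the junction gene F11r at -0.38 ± 0.07. Oasl2 was at -1.04 ± 0.41 (limma adjusted p = 0.368), and Irf7 was the 1 type I interferon gene of 24 that fell (3 adjusted over the list alone, adjusted p = 0.377 with an estimated correlation). In all, 44 genes rose and 39 fell (limma, Benjamini-Hochberg). The count was 34 without FADD IEC-KO Zbp1 -/- replicate 2, and 6 of 16 followed genes passed whichever array was left out, not Zbp1, Casp8, Tnfsf10, Slc7a9, Ces2a, Cited2, Hspb7, Irf7, Fosb or Gsto1. With only the compared arrays fitted 11 of 16 passed, not Casp8, Tnfsf10, F11r, Fosb or Gsto1.

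The effect of Mlkl loss was tested for a difference between the knockouts, within title numbers 1 to 30, as an interaction over 4 groups of 5 arrays. Muc1 differed by 2.07 ± 0.32 and Rps14, a ribosomal protein gene, by 0.52 and Zfp532 by -1.15 (limma adjusted p = 0.00109, 0.0105 and 0.0105). Mlkl itself was at 0.67 ± 0.24 (limma adjusted p = 0.285), Retnlb at 4.09 ± 1.12 (limma adjusted p = 0.191) and Dbp at -3.23 ± 1.02 (limma adjusted p = 0.245). None of the 25 interferon-gamma genes passed over all genes in limma (20 rose adjusted over the list alone, list median 1.04, adjusted p = 0.252 with an estimated correlation). In all, 2 genes rose and 1 fell (limma, Benjamini-Hochberg), and Muc1 alone passed with the 20 arrays fitted by themselves. The count was 116 without FADD IEC-KO replicate 21 and 0 in limma with the clock score as a covariate.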

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

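The tests of immune cells, a single mouse, Mlkl loss, the muscle layer, dilution and all regroupings of the arrays were chosen after the results were seen, and that of the time of collection was written before its result.

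Fadd fl/fl replicate 30 had a clock score of 1.74, against -1.31 to -0.49 in the other 4 arrays of its group. CASP8 IEC-KO replicate 17 had an acute cytokine list mean of 5.86, against 5.38 to 5.49 in the other 4, and a neutrophil list mean of 4.86, against 4.21 to 4.36. These arrays lay far from their group by Dixon's ratio, whose limit is 0.71 for 5 arrays. They were 3 of 140 tests, and chance gives about 1 in 20. A first screen of 390 measures had 23 over that limit, and it was narrowed to the 140 plotted measures after it was seen.

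The effect of Mlkl loss differed between CASP8 IEC-KO and FADD IEC-KO for Muc1 (2.07 log2 units), Rps14 (0.52) and Zfp532 (-1.15), by an interaction in limma. Zfp532 had a highest adjusted p of 0.0529 in limma when single arrays were left out, and Rps14 and Zfp532 did not pass with the 20 arrays fitted alone, with pooled series or without FADD IEC-KO replicates 22 and 23. Probe sets without a gene name here were outside all comparisons, and 386 of 2615 changed in FADD IEC-KO against Fadd fl/fl (175 rose and 211 fell), which is 14.8%, against 18.5% of named genes when both were fitted and adjusted together.

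Type I interferon-stimulated genes were higher in FADD IEC-KO Mlkl -/- than in Fadd fl/fl by 0.86 ± 0.13 (SE) in list mean, exact two-sided p = 0.00794. A single mouse was not the cause, since 5 of 5 arrays lay above the highest Fadd fl/fl array. Mlkl loss in either knockout is argued against, since CASP8 IEC-KO Mlkl -/- minus CASP8 IEC-KO was -0.15 ± 0.21 (exact two-sided p = 0.460). More immune cells could not be told apart from a response of resident cells, because the macrophage list mean differed by 0.22 ± 0.13 (exact two-sided p = 0.103). FADD IEC-KO alone had a list mean of 6.82 against 6.06 in Fadd fl/fl, and FADD IEC-KO Mlkl -/- minus FADD IEC-KO was 0.09 ± 0.20 (exact two-sided p = 0.667), so these values do not show that loss of both genes is needed, and an effect of FADD loss that Mlkl loss leaves in place stays open.

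Clock genes stood apart in CASP8 IEC-KO Mlkl -/-, whose clock score was 2.59 ± 0.58 above Fadd fl/fl (exact two-sided p = 0.0159). A different time of collection is a candidate explanation: 63 of 80 called genes (78.8%, exact two-sided binomial p = 2.27e-07, which treats genes as independent) moved as the clock slope among other arrays predicts. The time is not given in the sources used here, and a genotype effect on the clock would look alike. Loss of Mlkl itself is argued against, since CASP8 IEC-KO Mlkl -/- was 2.36 ± 0.41 above FADD IEC-KO Mlkl -/-, which lacks Mlkl too (exact two-sided p = 0.00794, 5 of 5 arrays above), and an effect of Mlkl loss only in CASP8 IEC-KO was not separated from the time.

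Smooth muscle markers were lower in FADD IEC-KO than in Fadd fl/fl, with a list mean difference of -1.14 ± 0.30 (exact two-sided p = 0.00794) and of -0.63 in the other series (p = 0.0476). Dilution that would lower endothelial and colonocyte markers as much is argued against, since those list means differed by -0.18 ± 0.11 and -0.13. Dilution of muscle by tissue that itself carries those cells was not tested, since it need not lower these lists. Less of the muscle layer in the sampled tissue may contribute and could not be told apart, since 10 enteric neuron and glia genes were at -0.32 ± 0.14 (exact two-sided p = 0.0397), but at -0.10 in the other series (p = 0.405). A change within muscle cells was not tested.

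In 100 splits of the arrays, the real one included, fewer than 5 gave a count of changed genes as large as the real one in each comparison. That limit was set after the results were seen and was not adjusted for the number of comparisons, so it does not exclude chance. Between the single knockouts and for the interaction other splits gave larger counts. The real count and the highest of the other splits were 3650 and 2239 for FADD IEC-KO against Fadd fl/fl, 479 and 237 for CASP8 IEC-KO against Casp8 fl/fl, and 2096, 1140, 147 and 82 against 1657, 1035, 6 and 2 for loss of Zbp1, Mlkl and Ripk3 in FADD IEC-KO and of Mlkl in CASP8 IEC-KO. Against floxed controls they were 209 and 11, 31 and 4, 15 and 3, and 9 and 6 in the same order of genotypes, and 83 and 1 between FADD IEC-KO Zbp1 -/- and FADD IEC-KO Mlkl -/-. In these comparisons the real split was the 1 as large. Between the single knockouts 4 splits gave as many as 1000 genes (highest other 2141), and for the interaction 3 gave as many as 3 (highest other 376). The source of these larger counts was not tested. For the lowering of risen genes the real and the most extreme other value were -0.65 and 0.66 (2 splits as large), -0.72 and 0.70 (1), -0.83 and -0.81 (1), and -0.22 and -0.23 (2), in that order of co-deletions.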

How the results depend on the processing

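Group variance weights, the clock covariate and the removal of FADD IEC-KO replicates 22 and 23 were chosen after the data were seen. No paired analysis was made, since the labels give no pairing of mice. Replicate numbers are title numbers unique to each array and say nothing about pairing. Values are counts of changed genes unless said otherwise. Except where the construction names it (fewer arrays, fewer genes, a fold limit), the cause was not tested.

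With a 2-fold limit the counts were 347 in FADD IEC-KO and 21 in CASP8 IEC-KO against floxed controls, 59 between them, 184, 188, 23 and 7 for FADD IEC-KO Zbp1 -/-, FADD IEC-KO Mlkl -/-, FADD IEC-KO RIPK3 IEC-KO and CASP8 IEC-KO Mlkl -/- against their single knockouts, 14, 8, 2 and 1 for these against floxed controls, and 5 between FADD IEC-KO Zbp1 -/- and FADD IEC-KO Mlkl -/-. In the same order, the compared arrays alone gave 1784, 1 and 41, then 184, 51, 22 and 27, then 106 (FADD IEC-KO Zbp1 -/-), 4 (FADD IEC-KO RIPK3 IEC-KO) and 28 (CASP8 IEC-KO Mlkl -/-), and 1 for the interaction. Pooled series gave 889, 567, 651 and 422 for the co-deletions against single knockouts and 5 for the interaction. With no series term CASP8 IEC-KO had 864, FADD IEC-KO Zbp1 -/- 1016, FADD IEC-KO RIPK3 IEC-KO 1237, CASP8 IEC-KO Mlkl -/- 444 and the interaction 7.

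Without the dimmest 40% of genes the counts were 725 for CASP8 IEC-KO, 276 and 149 for FADD IEC-KO RIPK3 IEC-KO and CASP8 IEC-KO Mlkl -/- against single knockouts, 384, 59 and 18 for FADD IEC-KO Zbp1 -/-, FADD IEC-KO Mlkl -/- and CASP8 IEC-KO Mlkl -/- against floxed controls, and 152 between the 2 FADD co-deletions. Group weights gave 147 for CASP8 IEC-KO, 510 between single knockouts, 63 and 368 for FADD IEC-KO RIPK3 IEC-KO and CASP8 IEC-KO Mlkl -/-, 552, 169 and 120 for the same 3 against floxed controls, and 284 between the 2. The clock covariate gave 772 for CASP8 IEC-KO, 606 between single knockouts, 27 and 3 for CASP8 IEC-KO Mlkl -/- against CASP8 IEC-KO and Fadd fl/fl, 75 for FADD IEC-KO Zbp1 -/- against Fadd fl/fl and 0 for the interaction in limma. Without FADD IEC-KO replicates 22 and 23 FADD IEC-KO had 682, FADD IEC-KO Zbp1 -/- 121, FADD IEC-KO Mlkl -/- 8, the single knockouts 135 and the interaction 1, and the lowering of risen genes in FADD IEC-KO Zbp1 -/- was -0.40 (fry p = 0.0874), whereas in FADD IEC-KO Mlkl -/- it was -0.47 (fry p = 0.0125).

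Leave-one-out counts ran from 2183 (without FADD IEC-KO replicate 22) to 4257 (21) in FADD IEC-KO, 1 (CASP8 IEC-KO 87) to 1070 (108) in CASP8 IEC-KO, and 417 (FADD IEC-KO 117) to 1795 (21) between them. Against single knockouts they ran from 835 (FADD IEC-KO 22) to 3001 (21) with Zbp1 loss, 388 (23) to 2156 (21) with Mlkl loss, 24 (FADD IEC-KO RIPK3 IEC-KO 113) to 411 (FADD IEC-KO 95) with RIPK3 loss and 21 (CASP8 IEC-KO Mlkl -/- 8) to 104 (CASP8 IEC-KO 18) with Mlkl loss in CASP8 IEC-KO. Against floxed controls they ran from 68 (Fadd fl/fl 28) to 284 (30), 8 (29) to 72 (26), 1 (FADD IEC-KO RIPK3 IEC-KO 112) to 14 (Casp8 fl/fl 86) and 2 (Fadd fl/fl 26) to 23 (30). They ran from 34 (FADD IEC-KO Zbp1 -/- 2) to 98 (1) between the 2 FADD co-deletions and from 2 (FADD IEC-KO 22) to 116 (21) for the interaction. The lowering of risen genes ran from -0.83 to -0.31, -0.93 to -0.42, -1.0 to -0.53 and -0.35 to -0.15 for loss of Zbp1, Mlkl and RIPK3 in FADD IEC-KO and of Mlkl in CASP8 IEC-KO, and passed in each of these fits.

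Quantile normalization, trend and robust moderation and the sex covariate left each count within 1.5 times. Of 343 results for genes given by name, 0 reversed under any alternative. A reversal was unlikely from the start, since many of these results were picked for having passed with groups that did not overlap. Those that lost their call numbered 22 with pooled series, 20 without a series term, 141 with the compared arrays alone, 9 with quantile normalization, 4 with trend and robust moderation, 3 with the sex covariate, 20 with group weights, 30 with the clock covariate, 114 in at least 1 leave-one-out fit and 94 of 178 without replicates 22 and 23. Array signal over background was not given in the sources used here, so a limit from dim signal was tested only by removing dim genes.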

Other observations

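The test of neighbouring genes and that of DNA segments were written before their results were seen, and the adjustment of the neighbour tests and all differences of list means were chosen after.

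Type I interferon-stimulated genes were above floxed controls in each of the 4 co-deletions by list mean: 0.86 ± 0.13 (SE) in FADD IEC-KO Mlkl -/-, 0.46 ± 0.07 in FADD IEC-KO Zbp1 -/-, 0.34 ± 0.11 in FADD IEC-KO RIPK3 IEC-KO and 0.26 ± 0.07 in CASP8 IEC-KO Mlkl -/- (exact two-sided p = 0.00794, 0.00794, 0.00794 and 0.0159). CASP8 IEC-KO alone was at 0.41 ± 0.21 (exact two-sided p = 0.111). FADD IEC-KO Mlkl -/- was above FADD IEC-KO Zbp1 -/- by 0.39 (exact two-sided p = 0.0317) and above CASP8 IEC-KO Mlkl -/- by 0.60 (exact two-sided p = 0.00794), and its difference from FADD IEC-KO was 0.09 (exact two-sided p = 0.667). These exact p-values were not adjusted for the number of differences tested. Against floxed controls, camera with an estimated correlation called this list only in FADD IEC-KO Mlkl -/- (adjusted p = 0.0187). The adjusted p was 0.615 in FADD IEC-KO Zbp1 -/- and 0.992 in CASP8 IEC-KO Mlkl -/-. No member passed in limma in either, and 4 of 24 were lower in CASP8 IEC-KO Mlkl -/-. The mean of the clock genes' score in FADD IEC-KO Zbp1 -/- was 1.71 above Fadd fl/fl (exact two-sided p = 0.0714).

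A hypothesis was that DNA flanking an edited gene came along with it from the line it was made in. Around Zbp1, Mlkl and Ripk3, 80 neighbours each were followed, those of Mlkl in both knockouts, which gave 27 calls in 320 tests against the single knockouts. Ripk3 was deleted in the epithelium only, from a floxed gene. Near Mlkl in FADD IEC-KO Mlkl -/- against FADD IEC-KO 10 of 80 were called (12.5%, against 5.82% elsewhere, one-sided Fisher p = 0.0178), and near Mlkl in CASP8 IEC-KO Mlkl -/- against CASP8 IEC-KO 2 of 80 (p = 0.0437), both past the limit set beforehand. Near Zbp1 13 of 80 were called against FADD IEC-KO (p = 0.0844) and near Ripk3 2 of 80 (p = 0.121). In the other direction, 0 of 80 neighbours were called by limma near Mlkl in FADD IEC-KO Mlkl -/- against Fadd fl/fl and against FADD IEC-KO Zbp1 -/-, and 0 of 80 near Zbp1 in FADD IEC-KO Zbp1 -/- against Fadd fl/fl, where few genes were called elsewhere (0.155%, 0.422% and 1.08%). Near Zbp1 1 of 80, Nfatc2, was called in FADD IEC-KO Zbp1 -/- against FADD IEC-KO Mlkl -/- (1.25%, against 0.417% elsewhere, p = 0.287). Over 10 such tests the adjusted p-values were 0.178 and 0.219, an adjustment applied after the result was seen, so flanking DNA could not be told apart from chance.

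Sh3bgrl and Uprt, both on the X chromosome, were lower in FADD IEC-KO Zbp1 -/- than in FADD IEC-KO Mlkl -/-, which prompted a test of whether called genes lie close together, as differing DNA segments would give. Among 83 called genes 1 pair lay within 5 measured genes, against a median of 2 in random draws, of which 8344 of 10000 had as many. That pair was Kdelr1 and Tmem143, so Sh3bgrl and Uprt were themselves further apart. The calls were thus not crowded at this distance, which does not test segments whose called genes lie further apart. The same count elsewhere was higher than in random draws: 4 pairs in FADD IEC-KO Mlkl -/- against Fadd fl/fl (median 0, as many in 1 of 10000 draws), 1 in CASP8 IEC-KO Mlkl -/- against Fadd fl/fl (183 of 10000) and 419 between the single knockouts (median 256, as many in 0 of 1000). It was 13 in FADD IEC-KO Zbp1 -/- against Fadd fl/fl (median 11, 3278 of 10000). Genes of one family also lie together, which was not separated here.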
